A study of Drosophila melanogaster with 4 samples.

How the data were processed

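Total RNA was isolated from larvae of the third instar with TRIZOL and sequenced from TruSeq RNA libraries, per the labels' protocols. The labels give 4 groups, normal and trisomy 2L females and males, and name 4 biological replicates for each, 16 in all. The submitters' processing notes name TopHat, HTSeq and the genome build dm3, with no versions or roles, and the annotation and strand setting are not given in the sources used here.

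The deposited tables hold CPM, made by the authors and averaged by them over the replicates of each group, per the file headers. One table covers autosomal genes (19047 transcript models) and the other X genes (3691). Each column sums to 1000000 over both tables together, so both share a single scale. No value is 0: in each column 373 to 645 transcript models carry the same value (2.22 CPM in normal females, 0.845 in normal males, 2.81 in trisomic females, 0.389 in trisomic males), and how it was set is not given in the sources used here. Differences near these values cannot be read as changes of expression. No whole reads could be recovered from averaged values, the depth per sample is unknown, and no interval that needs it was computed.

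Transcript models were averaged to 1 value per gene (14161 genes, 3962 of them with more than 1 model). Models of a gene, near-identical paralogs such as the trypsin, Jon, Mst84D and Lcp genes, and overlapping genes may share reads, so their single values are uncertain. The X and autosomal tables name genes and chromosome arms, and 13899 names (98.1%) were matched to a reference annotation of another genome release, used only for names, gene order and gene length. Of 13689 matched genes on the large arms and chromosome 4, 13680 lay on the same arm. Also, 5 genes named by a number were not interpreted.

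Changes were log2 of CPM plus a pseudocount of 1, which understates changes of low genes. Arms were compared by the median over genes less the median of 2R, 3L and 3R genes, a difference that library scaling alters only through the pseudocount. Genes at least 1.5-fold different between karyotypes, or 2-fold between sexes, were counted by size. For gene lists, the percentile of the median among 10000 random lists, drawn within 20 bins of mean level (seed 1), describes these group means and is no test across animals. A median was called outside random lists beyond the percentiles 2.5 and 97.5. Random lists had the size of the full list and were drawn from all arms, with the members of the list itself included. Limits printed beside medians without 2L members are therefore only a guide. The steps were tested on simulated data of 6378 genes: a 2L shift of 0.5 put in was recovered as 0.47 in females and in males.

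The 22 gene lists and the comparisons were fixed before the data were examined, and the design foresaw no test if the columns were group means. These choices were made after the values had been seen: the mean of at least 10 CPM, in place of a filter that needs counts; the mean over transcript models; the size classes in place of a false discovery rate; and random lists in place of a set test. Arm medians under minimum means of 0, 5, 10 and 20 CPM had been looked at before 10 was settled, and in females the 2L excess rises with each stricter minimum, while in males it is smallest with none and largest at 20. The alternatives with a 2-fold threshold and with rescaling over genes were removed and then restored after their values had been seen, and are reported in full.

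Named genes followed a rule written beforehand: per sex the 5 largest increases and decreases with a mean of at least 10 CPM, the 5 most abundant 2L and X genes past the threshold, all members of the MSL and sex determination lists, and 3 members of each other list that stood out, with the 5 extremes of each direction for the difference between sexes and for sex bias. Its requirements on the false discovery rate and on replicate overlap could not be applied, and 1.5-fold, or the largest change within a list, replaced them. Chosen after their values were seen were dj, Lsp2, ng3, Rpn1, Yp3, epsilonTry, Cpr49Ac, Lcp1, Lcp2 and the genes of the closing section's other families.

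Not run, because the columns are group means, were all tests on counts or replicates, the test of the interaction, permutation tests of arms, tests of single genes against 1.5-fold and 0.67-fold, the replicate split for sex-biased genes, leaving out replicates, replicate blocks and set tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.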

Results

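RNA was measured in larvae of Drosophila melanogaster, at the third instar, that carried either the normal chromosome complement or a trisomy of 2L, the left arm of chromosome 2, so that 2L genes were present in 3 copies instead of 2. Females and males of both karyotypes were collected, which gave 4 groups, and the labels name 4 biological replicates in each. The values analysed are the authors' mean CPM of each group, with 1 value per gene and group. They are shares of a total over all transcript models, in which a gene with several models can count more than once. No replicate values were analysed here and the depth of the libraries is unknown, so differences below are sizes of authors' means with no test, error or p-value. A total of 6308 genes out of 14161 had a mean of at least 10 CPM over the 4 groups. Changes are log2 of CPM + 1 in trisomic against normal larvae of the same sex. Because CPM are shares of a total, a higher share of 2L lowers all other shares, by a log2 of -0.12 in females and -0.13 in males. The median over the 4069 genes of 2R, 3L and 3R was lower than that, at -0.20 and -0.31. How much of this gap is a fall of those genes is open, because the column totals count each transcript model. Summed over 1 value per gene, CPM were 528401 in normal and 495582 in trisomic females, and 524303 and 491158 in males.

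The comparison of trisomic with normal females asked which genes differ in level between the karyotypes. Strain and exact stage are not given in the labels and cannot be separated from karyotype, here or in males. Genes of larval muscle, glycolysis, haemocytes and antimicrobial defence had higher levels in trisomic females, while the glue protein genes of the salivary gland had lower ones. Myosin heavy chain (Mhc, on 2L) stood at 1066 CPM against 263 CPM in normal females, a log2 change of 2.02. The glue gene Sgs8 stood at 157 CPM against 944 CPM, a change of -2.58. In all, 968 genes were at least 1.5-fold higher and 1154 at least 1.5-fold lower, and relative to the median of 2R, 3L and 3R genes these counts became 1407 and 474. At least 2-fold higher and lower were 342 and 187 on the deposited scale. The direction of the imbalance therefore rests on the scaling and on the threshold.

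The largest increases in females were those of CG3819 (3.32 to 212 CPM, log2 change 5.63), CG33267 (0.897 to 65.9 CPM, 5.14), CG9463 (5.44 to 151 CPM, 4.56), CG6271 (1.99 to 52.6 CPM, 4.16) and the larval cuticle gene Lcp65Ag1 (0.655 to 22.9 CPM, 3.85). The largest decreases after CG9040 (47.8 to 7.16 CPM, -2.58) and Sgs8 were those of CG16762 (-2.50), CG5246 (-2.43) and CG13461 (-2.41). Of the most abundant 2L genes with at least a 1.5-fold difference, the storage protein gene Lsp1beta stood at 23835 against 14926 CPM (0.68) and the digestive protease gene Jon25Biii stood at 2881 against 1283 CPM (1.17). CG6770 (-0.64), CG8997 (-0.84) and CG7916 (-1.29) were lower although they lie on 2L. Among abundant X genes the storage protein gene Lsp1alpha was higher (1.63), and Sgs4 (-1.80), RpL37a (-0.60), RpS15Aa (-0.70) and Cyp1 (-0.64) were lower.

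Gene lists fixed before the data were examined were set against 10000 random lists of the same size and similar level. All 12 glycolysis genes were higher in trisomic females, 8 of them at least 1.5-fold, with a median of 0.81. Enolase (Eno, 2.02), phosphofructokinase (Pfk, 1.70) and phosphoglycerate kinase (Pgk, 1.69) led this list. Of 22 muscle genes 19 were higher, with a median of 0.75, and alpha-actinin (Actn, 1.86) and Mlp84B (1.76) followed Mhc. Haemocyte markers had a median of 1.19, with 12 of 13 genes higher, led by the collagen IV genes vkg (2.24) and Cg25C (2.10) and by the prophenoloxidase gene CG8193 (1.73). The antimicrobial list had a median of 1.07 over 8 genes, among them Dpt (6.78 to 70.5 CPM, 3.20), DptB (2.20) and Def (2.05). Larval serum and fat body genes had a median of 0.53, with Tsf1 at 1.09 and fat-spondin at 0.93, but Lsp2 was lower (-0.81). Oxidative phosphorylation genes had a median of 0.21, with RFeSP (1.33), CG3731 (1.14) and ND75 (1.12) highest. Each of these medians lay above the central 95 percent of random lists, though that of oxidative phosphorylation only just, as the upper limit was 0.21, and it fell to 0.11 without the 7 of its 29 genes that lie on 2L. Without their 2L members the medians were also smaller for larval serum and fat body genes (0.31, 6 of 14 on 2L, upper limit 0.29), glycolysis (0.66), muscle (0.62) and haemocyte markers (0.93). With no filter muscle genes had a median of 0.53, haemocyte markers 0.94 and the antimicrobial list, of whose 26 members 8 had been kept, 0.97.

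The glue list had a median of -1.64 in females over the 9 of its 21 members that reached the mean of 10 CPM, with 7 of them at least 1.5-fold lower, Sgs5 (-2.02) and Sgs7 (-1.87) among them, and ng3 higher (1.10). With no filter its median was -0.41 in females and -1.04 in males. Of 30 proteasome genes 22 were lower, with a median of -0.52, among them Pros25 (-0.94), Rpn12 (-0.86) and Prosbeta3 (-0.85), while Rpn1 was higher (0.71). Cytochrome P450 genes had a median of -0.42 over 35 of 71 members, or -0.11 with no filter, from -2.39 for Cyp4e3 to 2.54 for Cyp309a1, and Cyp6a23 stood at 114 against 456 CPM. These 3 medians lay below the central 95 percent of random lists. Inside that range in females lay cytosolic ribosomal proteins (-0.44), glutathione S-transferases (-0.31), sex determination (-0.38), germline and ovary genes (-0.35), DNA damage and apoptosis (-0.18), midgut digestive enzymes (-0.16), neuronal markers (-0.11), histone modifiers and chromatin (-0.10), ecdysone response (-0.06), heat shock and chaperones (-0.02), testis and spermatocyte genes (0.15) and larval cuticle (0.20). Relative to the 2R, 3L and 3R median, the signs of the midgut, neuronal, chromatin, ecdysone, heat shock and DNA damage lists turned. The ribosomal median lay only just inside (-0.442, lower limit -0.444). Random lists of its level could draw the ribosomal genes themselves, and their median was -0.28. Its place inside the range therefore cannot decide whether the ribosomal list stood out. Without 2L members the ribosomal (-0.54), sex determination (-0.60) and DNA damage (-0.49) medians passed the lower limits of their full lists (-0.44, -0.56 and -0.45). The other medians inside the range stayed there. Most testis and spermatocyte genes passed the filter only through males and are barely measured in females, as dj (0.261 CPM in normal and 0.342 CPM in trisomic females). The pseudocount holds their female change near 0, so the place of that list among random lists carries little information in females.

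**Figure D1:**
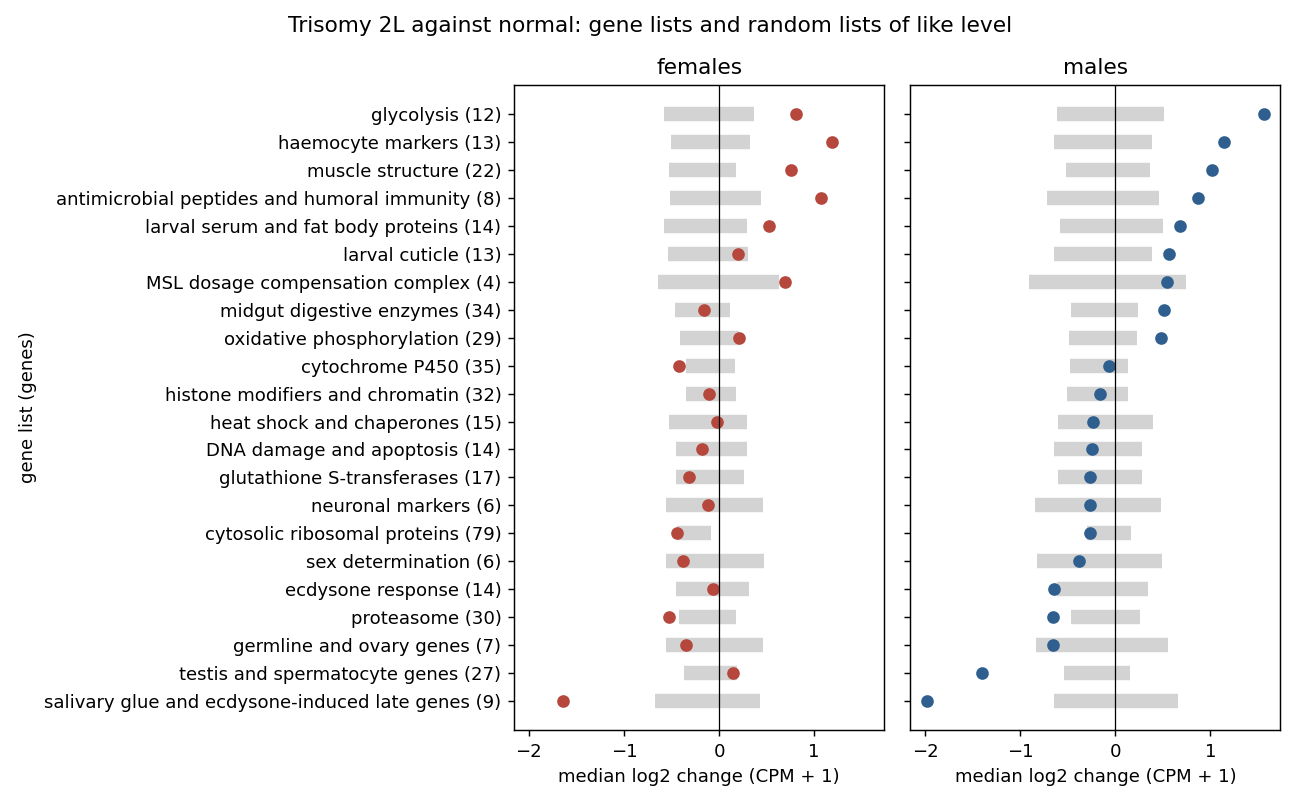
Median log2 change (CPM + 1) of each gene list, trisomic against normal females (left) and males (right), with the number of genes in parentheses; grey bars span the central 95 percent of 10000 random lists of similar level. Glycolysis lies at 0.81 and 1.56, and the glue list at -1.64 and -1.98. The testis list lies at 0.15 in females, where most of its genes are barely measured, and at -1.40 in males.

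Trisomic males were compared with normal males in the same way. Most groups that stood out in females did so again, and in addition genes of the testis and of spermatocytes were lower. Glycolysis had a median of 1.56, with all 12 genes at least 1.5-fold higher, and enolase stood at 670 against 106 CPM (Eno, 2.65). Sgs8 stood at 129 against 986 CPM (-2.93), and the testis gene dj at 28.99 against 113 CPM (-1.92). In all, 1073 genes were at least 1.5-fold higher and 1863 at least 1.5-fold lower, and relative to the 2R, 3L and 3R median 1742 and 913.

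CG3819 (6.19), CG33267 (5.87), CG9463 (5.15), CG12506 (4.90) and CG9466 (4.35) had the largest increases in males. CG34244 (-3.04), Sgs8, CG13606 (-2.62), CG13898 (-2.60) and CG11892 (-2.56) had the largest decreases. Lsp1beta stood at 24799 against 14782 CPM (0.75) and Jon25Biii at 3243 against 852 CPM (1.93). CG6770 (-0.68), CG8997 (-0.65) and CG7916 (-0.91) were lower in males too. On the X, Lsp1alpha (0.96), CG8664 (0.60), the ribosomal gene sta (0.88) and Gapdh2 (0.78) were higher and Sgs4 was lower (-1.98).

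Muscle genes had a median of 1.02 in males, with 16 of 22 at least 1.5-fold higher, among them Mhc (2.51), troponin T (up, 2.36) and Mlp84B (2.33). Haemocyte markers had a median of 1.14 (CG8193 2.39, vkg 2.33, Cg25C 2.19), the antimicrobial list 0.87 (Dpt 3.11, DptB 2.22, Def 1.68), larval serum and fat body genes 0.68 (Tsf1 1.91, CG15828 1.10) and oxidative phosphorylation 0.48 (RFeSP 2.01, CG3731 1.65, CG4169 1.57). Pgk (2.40) and the pyruvate kinase gene PyK (2.24) followed Eno. Without their 2L members the medians of larval serum and fat body genes (0.54) and oxidative phosphorylation (0.45) were smaller, and with no filter those of muscle (0.89) and haemocyte markers (0.88). Midgut digestive enzymes (0.51) and larval cuticle genes (0.56) also lay above random lists in males. The cuticle median rests on the 13 of 35 members that passed the filter and was 0.11 with no filter. CG8693 (3.48), the amylase gene Amy-p (3.15) and Jon25Bii (3.05) led the midgut list, and Cpr47Eg (4.25), Lcp65Ag3 (3.90) and Lcp65Ag1 (3.89) the cuticle list. These cuticle genes lay between 0.320 and 3.81 CPM in normal males. Of 34 midgut genes 25 were higher and 9 lower, epsilonTry (-2.01) the most. Of the 13 cuticle genes 10 were higher and 3 lower, namely Cpr49Ac (-1.48), Lcp1 (-1.06) and Lcp2 (-0.80).

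Of 27 testis and spermatocyte genes, out of 44 in the list, 23 were at least 1.5-fold lower in trisomic males, with a median of -1.40, and Mst84Dd (-2.02), CG7045 (-2.02) and Mst84Db (-1.97) were lowest. With no filter the median was -0.93. The glue list (-1.98; Sgs7 -2.23, Sgs5 -2.18), the proteasome (-0.65; Prosbeta3 -1.27, Pros25 -1.23, Rpn12 -1.23) and the ecdysone response list (-0.64; ImpE2 -1.21, ImpE3 -1.19) lay below random lists. ImpL3, the lactate dehydrogenase gene that both the ecdysone and the glycolysis lists hold, was higher (2.09). Inside the range of random lists in males lay germline and ovary genes (-0.66), sex determination (-0.38), cytosolic ribosomal proteins (-0.27), neuronal markers (-0.27), glutathione S-transferases (-0.26), DNA damage and apoptosis (-0.25), heat shock and chaperones (-0.23), histone modifiers and chromatin (-0.16), cytochrome P450 (-0.07) and the MSL complex (0.55). Relative to the 2R, 3L and 3R median, the signs of the ribosomal, neuronal, glutathione S-transferase, DNA damage, heat shock, chromatin and cytochrome P450 lists turned. Without 2L members the ribosomal median in males was -0.44, past the lower limit of the full list (-0.30). As in females, random lists could draw the ribosomal genes themselves, so the place of the full list inside the range cannot decide. Neuronal markers (-0.66, lower limit -0.84) and DNA damage genes (-0.53, lower limit -0.64) were also lower without them but stayed inside.

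The position of the genes was then compared, to ask how far the level of 2L genes followed their copy number and whether genes elsewhere moved. Genes of 2L were higher than those of the other large autosomal arms in both sexes, and the median excess, computed with a pseudocount of 1, was smaller than the 1.5-fold ratio of gene copies. Over 1270 genes the 2L median was 0.19 in females and 0.10 in males, which relative to 2R, 3L and 3R is 0.39 (1.31-fold) and 0.41 (1.32-fold). Without a pseudocount the median excess differed with the mean level in the sex concerned: in females it was 1.46-fold at 5 to 10 CPM, 1.29-fold at 10 to 20, 1.43-fold at 20 to 50, 1.503-fold at 50 to 100 and 1.49-fold at 100 CPM or more, and in males 1.38-fold, 1.25-fold, 1.38-fold, 1.43-fold and 1.35-fold. Summed over all genes of the arms, the corresponding log2 ratios were 0.56 and 0.55. Such sums give abundant genes the most weight. Among these are Lsp1beta on 2L (14926 to 23835 CPM in females) and Lsp2 on 3L (18488 to 10577 CPM), with the same directions in males. The share of all CPM from 2L, counting each transcript model, was 19.9% in normal and 26.4% in trisomic females, and 20.04% and 26.9% in males. With 1 value per gene it was 20.9% and 27.5% in females, and 21.4% and 28.1% in males. Of the 2L genes, 748 (58.9%) in females and 733 (57.7%) in males lay above the midpoint between no change and 1.5-fold, relative to 2R, 3L and 3R, against 32.2% and 35.7% of the genes of those arms.

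The excess ran along the whole of 2L. In each of 25 windows of consecutive genes the 2L median exceeded the 2R, 3L and 3R median, by 0.12 to 0.85 in females and 0.09 to 1.06 in males. The window from nAcRbeta-21C to chinmo was highest in both sexes. On 2R, 12 of 25 windows lay above 0 in either sex, and the window next to the centromere, from CG17683 to CG7845, was lowest at -0.51 and -0.53.

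**Figure D2:**
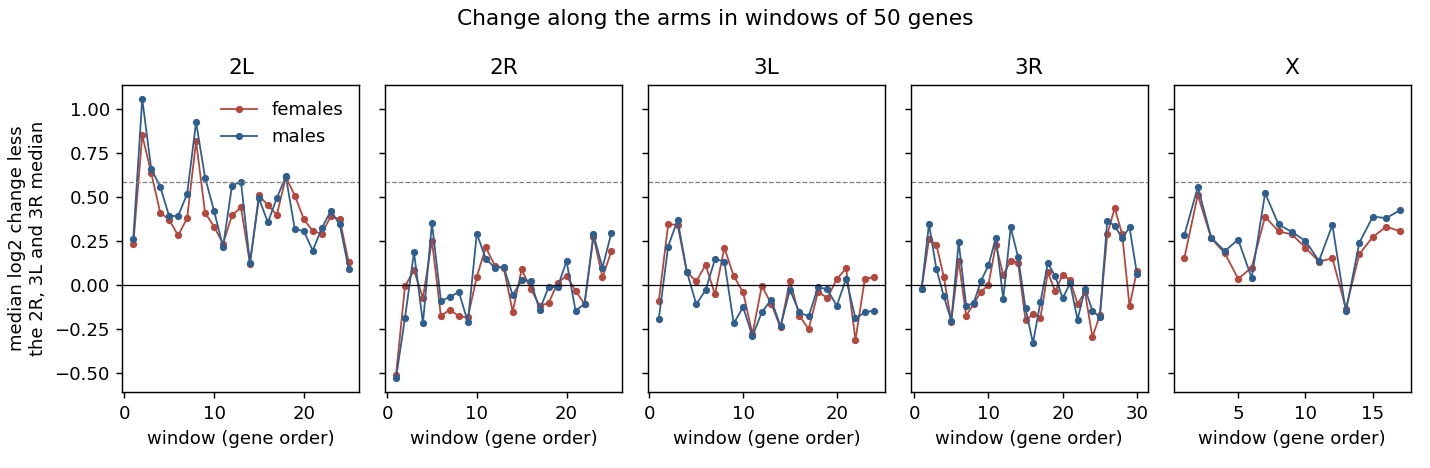
Median log2 change (CPM + 1) in windows of 50 genes (46 in the last of 2L) in chromosomal order, less the median of 2R, 3L and 3R genes. Females are red and males blue, and the dashed line marks 1.5-fold. All 25 windows of 2L lie above 0, from 0.12 to 0.85 in females and 0.09 to 1.06 in males.

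Genes of the X had a median change of 0.02 in females and -0.03 in males over 875 genes, which relative to 2R, 3L and 3R is 0.22 (1.16-fold) and 0.28 (1.22-fold). Among X genes of at least 100 CPM the difference was -0.02 in 96 genes in females and 0.04 in 89 genes in males, computed without a pseudocount. Chromosome 4, the small autosome rich in heterochromatin, had medians of -0.47 and -0.56 over 59 genes. Genes placed in heterochromatin had the lowest medians, -0.67 and -0.68 over 33 genes. Of the 2R, 3L and 3R genes, 31.0% in females and 34.8% in males lay below the midpoint between no change and 0.67-fold, after centring on their own median. Above the opposite midpoint, towards 1.5-fold, lay 32.2% and 35.7%. These shares describe the spread around the median, since centring removes any common shift.

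**Figure D3:**
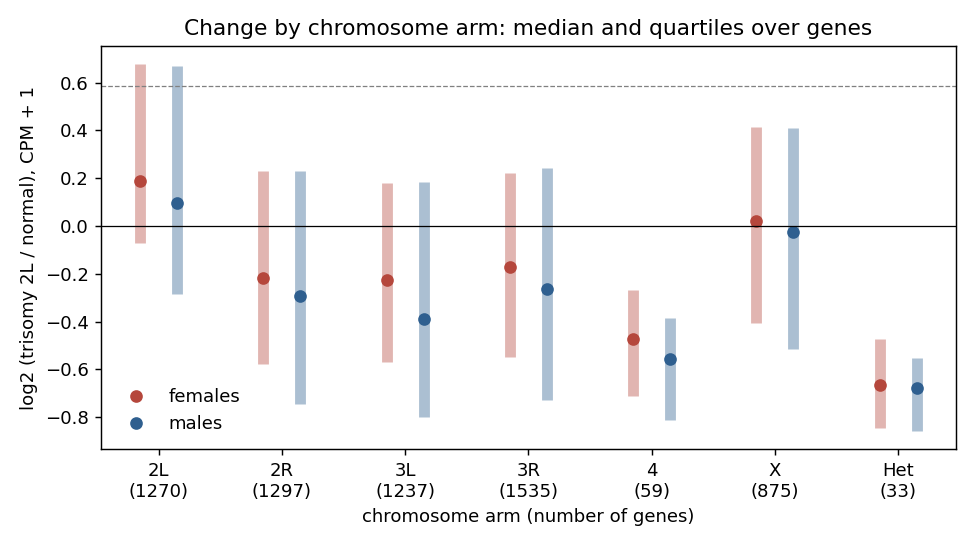
Log2 change (CPM + 1) of trisomic against normal larvae by chromosome arm; points are medians over genes, bars span the quartiles, numbers of genes stand in parentheses, Het is genes placed in heterochromatin, and the dashed line marks 1.5-fold. The 2L medians are 0.19 and 0.10 and the chromosome 4 medians -0.47 and -0.56 in females and males.

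The MSL complex raises transcription of the male X, and its protein and RNA genes were examined in the 4 groups. The 2L genes msl-1 and msl-2 were higher in trisomic larvae of both sexes. The log2 change of msl-2, whose protein is made in males, was 0.89 in females (5.59 to 11.2 CPM) and 0.91 in males (15.5 to 29.98 CPM), and that of msl-1 0.67 and 0.66. The noncoding RNA gene roX1 went in opposite directions, from 13.1 to 22.4 CPM in females (0.73) and from 506 to 285 CPM in males (-0.82). roX2 was lower in males (10.96 to 6.48 CPM, -0.68) and lay under 1 CPM in females (0.25). The helicase gene mle was higher (0.32 and 0.43), and msl-3 (-0.10 and 0.04) and mof (0.04 and -0.21) changed less than the shift of the autosomal median. Over the 4 members with a mean of at least 10 CPM the list median was 0.70 in females, above random lists (upper limit 0.63). Of these 4, msl-1 and msl-2 lie on 2L. Without them the median was 0.52 in females and -0.19 in males, against 0.55 in males with them. No random lists were drawn for this remainder, so the limit for all 4 cannot judge it. With no filter, over all 7, the medians were 0.32 and 0.04.

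**Figure D4:**
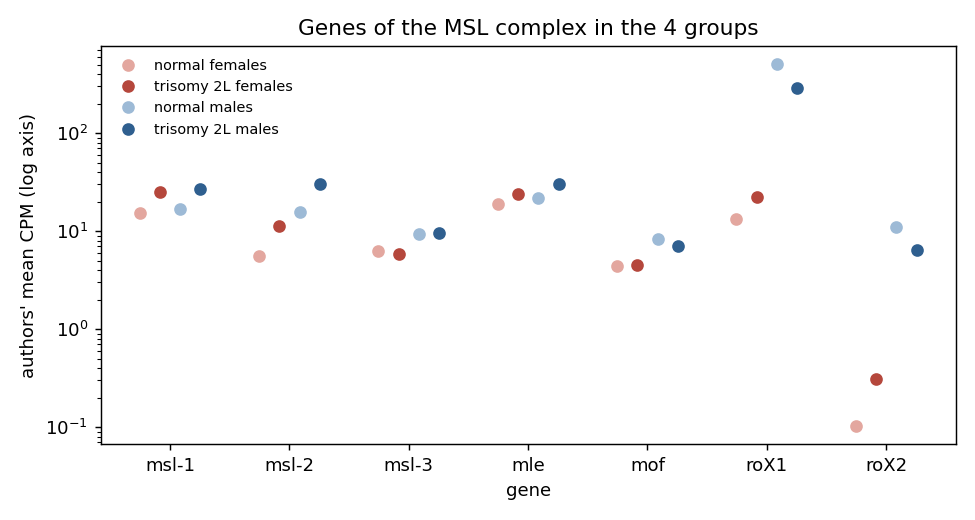
Authors' mean CPM (log axis) of the 7 genes of the MSL complex in the 4 groups, 1 value per gene and group. roX1 stands at 506 CPM in normal males and 285 CPM in trisomic males, and at 13.1 and 22.4 CPM in females.

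Among sex determination genes, Sxl, the switch gene of female development, was lower in both sexes (-0.60 and -0.52), as were its partner snf (-0.72 and -0.72), tra (-0.70 and -0.75), tra2 (-0.69 and -0.86) and ix (-0.79 and -0.89). The splicing cofactor genes vir (0.74 and 0.60) and fl(2)d (0.36 and 0.39) and fru (0.24 and 0.35) were higher. her (-0.17 and -0.25) and dsx (-0.03 and -0.34) differed less, and run (0.19 and 0.14) and sisA (-0.92 and 0.06) lay at or below 1.31 CPM in every group. Relative to the 2R, 3L and 3R median, her turned above 0 in both sexes and dsx in females.

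The 2 sexes were compared to ask whether they responded alike. Across 6308 genes, which are not independent replicates, the female and male changes had a Pearson r of 0.81 and a Spearman rho of 0.78. Without genes at least 2-fold higher in normal males these were 0.899 and 0.887 over 5720 genes. Of the genes at least 1.5-fold higher, 782 were so in both sexes, where 165 would be so if the lists were independent, and 960 were lower in both, against 341. The female and male comparisons share no group. The male change lay at least 2-fold above the female change in 62 genes and at least 2-fold below it in 361, of which 318 were at least 2-fold higher in normal males than in normal females. CG14205 (-0.92 in females, 0.73 in males), lcs (1.39, 2.98), Jon25Bii (1.54, 3.05), Cyp4e3 (-2.39, -0.91) and CG16762 (-2.50, -1.04) differed most in the first direction. CG13477 (1.16, -1.67), CG13898 (0.09, -2.60), the protamine gene Mst35Ba (1.24, -1.38), CG17470 (1.35, -1.01) and eIF4E-3 (0.82, -1.53) differed most in the other, and their female values lay between 0.0736 and 2.49 CPM.

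Normal males and normal females were compared as the baseline of sex bias. Among the 6308 genes with a mean of at least 10 CPM, those at least 2-fold higher in males numbered 588 and those at least 2-fold higher in females 33. The largest male excess was in CG12699 (367 against 0.801 CPM, log2 difference 7.68), SIP2 (7.55), CG32063 (7.39), CG32064 (7.33) and CG6372 (7.24). The largest female excess among them was in CG4500 (122 against 20.6 CPM in males, -2.51), Nplp2 (-1.89), lcs (-1.77), CG7763 (-1.55) and CG14425 (-1.49). Yp3, outside these filtered genes, had a larger one (6.99 against 0.277 CPM, -2.64).

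The male-high genes were then followed into the trisomic larvae. Their median change was -1.17 in males, with 532 of 588 lower and 458 at least 1.5-fold lower, and 0.07 in females. Most of these genes are barely measured in females, with a median of 0.412 CPM in normal and 0.576 CPM in trisomic females, so the pseudocount holds their female change near 0 and the contrast between the sexes carries little information. CG12699 stood at 120 CPM in trisomic males (-1.61) and SIP2 at 101 CPM (-1.77). Because the normal male values both selected these genes and entered their change, the genes were also selected in trisomic larvae, which biases the other way, and the median over those 487 genes was -1.27. Relative to the 2R, 3L and 3R median the first value was -0.86.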

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

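Of the tests in this part, the library scaling test and all tests of mixing except that on 33 female-high genes were chosen after the result they bear on had been seen.

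A set of 6 named genes changed by at least 1.5-fold in opposite directions in the sexes, and none of these differences was tested, since each group has 1 value per gene. The male change less the female change was -2.83 for CG13477, 1.65 for CG14205, -2.36 for CG17470, -2.62 for Mst35Ba, -2.35 for eIF4E-3 and -1.55 for roX1. The female values of CG13477, CG17470, Mst35Ba and eIF4E-3 lie between 0.0736 and 2.49 CPM, below the value that many transcript models share in their column (2.22 CPM in normal and 2.81 CPM in trisomic females).

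Testis and spermatocyte genes were lower in trisomic males, and scaling of the libraries is argued against, since the list lay -1.09 from the 2R, 3L and 3R median. Mixing of females into the trisomic male libraries would need a share of 52.98% females, and the criterion set for it beforehand was met, as 33 genes female-high in normal larvae had a median male minus female difference of -1.10 there and -0.17 in trisomic larvae (-0.42 predicted), but 26 genes female-high in trisomic larvae had -1.40 there and -0.05 in normal larvae, so selection alone can give such a loss and the test was set aside as undecided after its values had been seen. Nplp2 (-1.89 in normal larvae, -0.47 in trisomic larvae, -0.61 predicted), lcs (-1.77, -0.18, -0.58), roX1 (5.16, 3.61, 4.12) and roX2 (3.44, 2.51, 2.49) lost sex difference as mixing would have it, while 5 Sxl transcript models (-1.50, -1.43, -0.52), CG4500 (-2.51, -2.35, -0.71), CG7763 (-1.55, -1.89, -0.53), CG14425 (-1.49, -1.43, -0.52) and msl-2 (1.33, 1.34, 0.77) did not, and of 3563 genes with at least 20 CPM in trisomic females 10 lay more than 1.5-fold under the lowest male level that this share allows, Yp3 among them (0.799 CPM in trisomic males, 23.7 CPM in trisomic females). These genes go both ways, were chosen afterwards and have no replicate spread to set them against, so mixing stays open. A smaller share of testis tissue cannot be told apart from lower transcription within it: the 242 genes at least 32-fold higher in normal males had an interquartile range of 0.52, close to the 0.5 set as the bound for a common factor, and medians of -1.18 on 2L and -1.62 on 2R, 3L and 3R; karyotype, strain and stage remain untested.

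Genes of chromosome 4 and heterochromatin were lower in both sexes, 75 of 92 of them below the 2R, 3L and 3R median in both. Low expression does not account for it, since with a mean of at least 20 CPM the weaker of the female and male differences was -0.30. Nor does gene length, since against genes of similar length and level the weaker difference was -0.35. A difference in strain or developmental stage between trisomic and normal larvae, which the design does not separate from karyotype, stays open and untested.

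X genes were high relative to 2R, 3L and 3R. Loss of testis transcripts is argued against, since without genes 2-fold higher in normal males the difference in males was 0.23. A different mix of expression levels is argued against, since against genes of similar level the smaller of the female and male differences was 0.21. The excess was absent in X genes of at least 100 CPM (-0.02 in females and 0.04 in males), so it does not hold at every level, and an effect of karyotype, strain or stage stays open.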

How the results depend on the processing

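The alternatives with a 2-fold threshold, a mean of at least 20 CPM, rescaling over genes, centring, the largest transcript model, members outside 2L, selection in trisomic larvae and removal of male-high genes were chosen after seeing the data. So were other pseudocounts for arm medians, lists and the change of male-high genes, no filter and a mean of at least 5 for lists and for that change, and no filter and pseudocount 0.1 for the Pearson r. In these alternatives no arm median relative to 2R, 3L and 3R, no list outside the random range and no named gene at least 1.5-fold different changed sign. Lists inside that range did in 24 alternatives, over 15 list medians, among them MSL in males (0.55, -0.19 outside 2L), cytochrome P450 in males (-0.07, 0.12 with no filter) and chromatin in females (-0.10, 0.03 with no filter), as did named genes with smaller changes in 3 alternatives. The balance of higher and lower genes also turned in females at 2-fold, centred and rescaled, and in males centred. Of 129 alternatives to the main values, 80 stayed within the set tolerance and 49 moved; for the other values 2056 stayed and 73 moved. The 73 are 45 for single genes, 19 for lists, 1 for the Pearson r (0.81, 0.62 with no filter) and 8 of 9 for the female change of male-high genes (0.07, from 0.02 with pseudocount 5 to 0.27 centred). The tolerance for a median is a binomial interval over genes, not replicate error, and it is wide for short lists. Staying within the tolerance therefore does not by itself show stability. MSL in males and the glue list in males (-1.98, -1.04 with no filter) count as having stayed. So do the 1407 genes at least 1.5-fold higher in females once centred, against 968 on the deposited scale. Causes were not tested unless the alternative itself changes the genes or threshold counted. No paired analysis was possible because the columns are group means without replicate numbers; leaving out replicates, blocks, other normalization factors and count or set tests were not run for the same reason, and the unknown depth leaves the precision of every value open.

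2L relative to 2R, 3L and 3R stood at 0.39 in females and 0.41 in males. It was 0.45 in females as a mean over genes; 0.56 and 0.55 as a ratio of sums; 0.20 and 0.24 with no filter; 0.34 in females at a mean of at least 5; 0.47 and 0.47 at 20; 0.47 in females with pseudocount 0.1 and 0.30 with 5; and 0.46 in females without male-high genes. The X stood at 0.22 and 0.28, and moved to 0.10 and 0.17 with no filter and to 0.21 in males as a ratio of sums.

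Genes at least 1.5-fold higher and lower were 968 and 1154 in females, 1073 and 1863 in males. With no filter they were 2001 and 2020, 1767 and 3738. At 2-fold they were 342 and 187, 533 and 695. Centred, 474 were lower in females, and 1742 higher and 913 lower in males. Rescaled over genes, 1528 and 1644 were higher in females and males. At a mean of at least 20, 1136 were lower in males.

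The male change lay 2-fold above the female change in 62 genes and below in 361. With no filter these were 224 and 1384, and rescaled 94 and 665. Below were 685 at a mean of at least 5 and 157 at 20. Above were 31 with pseudocount 5 and 108 centred. Genes 2-fold higher in normal males, 588, were 2026 with no filter, 1140 at a mean of at least 5, 233 at 20 and 1138 rescaled. Those higher in normal females, 33, were 437 with no filter and 15 with pseudocount 5. The change of male-high genes in males, -1.17, was -1.06 with no filter, -1.08 with pseudocount 5, -1.10 rescaled, -1.07 rescaled with the genes held fixed, -0.86 centred, -1.27 selected in trisomic larvae and -1.35 over 4-fold.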

Other observations

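The families in this part were chosen after the values had been seen, so their place among random lists is a description and lends no support. All 8 basement membrane genes kept were at least 1.5-fold higher in both sexes. Their medians were 1.47 in females and 1.15 in males, above the central 95 percent of random lists. Members named but not among the genes kept were wb and SPARC here, and Mdh2 of the tricarboxylic acid cycle. The laminin genes LanA (1.09, 0.82), LanB1 (1.28, 0.95) and LanB2 (1.40, 1.01), nidogen (Ndg, 1.77, 1.29) and perlecan (trol, 1.03, 0.88) were among them, and vkg, Cg25C and Pxn also belong to the haemocyte list. Genes of the tricarboxylic acid cycle had medians of 0.75 and 0.83 over 9 genes, with citrate synthase (kdn, 1.44, 1.90) and aconitase (Acon, 1.12, 1.58) high and Idh lower (-0.23, -0.07), though above 0 once centred on 2R, 3L and 3R in males. SdhA, SdhB and SdhC also belong to the oxidative phosphorylation list, and without its 2L member the median was 0.51 in females (upper random limit 0.46) and 0.77 in males. Both lists lay above random lists in both sexes.

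Aminoacyl-tRNA synthetase genes had medians of 0.18 and 0.39 over 17 genes, above random lists in males (upper limit 0.29). Without the 3 members on 2L the male median was 0.28, under that limit, which was drawn for all 17 genes. Mitochondrial ribosomal protein genes (-0.27, -0.29), vacuolar ATPase genes (-0.18, -0.02), replication licensing and clamp loading genes (-0.22, -0.09) and odorant-binding protein genes (-0.49, -0.62) lay inside the range of random lists. The testis form Vha100-3 stood at 39.7 CPM in normal and 11.4 CPM in trisomic males.

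Male-high genes on 2L were less low in trisomic males than those elsewhere, by about as much as 2L genes in general. The median change of the 155 on 2L was -0.90, and that of the 390 on 2R, 3L and 3R was -1.32, while over all genes the 2L median in males lay 0.41 above that of 2R, 3L and 3R. This difference was not tested across animals.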
